A study of Glycine max with 36 samples.

How the data were processed

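RNA-seq was made from unifoliolate leaves, the first pair of simple leaves above the cotyledons, of soybean (Glycine max, cultivar Williams 82). Per the labels' protocols, seedlings grew for 9 days at 28 °C under cycles of 16 h light and 8 h dark, were then moved to constant conditions and were sampled from an age of 11 days. Samples were taken every 4 h over 44 h, which gives 12 time points written here by their zeitgeber time in h, from ZT0 to ZT44, as the labels give it. Each time point had 3 biological replicates, and each replicate pooled leaves of 3 seedlings. The groups are the 12 time points. Different seedlings were taken at each time, so the 3 replicates measure the spread between pools of plants.

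The authors deposited 1 table of FPKM values, which scale fragments by the length of the gene and by the mapped total, with 47011 gene identifiers and 36 columns, and each column name matched the title of 1 sample. TopHat2 2.1.0 and HTSeq 0.6.0 are named per the submitters' processing notes, which give neither their roles nor their order. The tool that computed the FPKM, the genome build and the annotation are not given in the sources used here. Each value is a share of its library and a few abundant transcripts can move the values of all others. The values are not counts, and no count model was used. None of the 47011 identifiers (0) matched the 59048 genes of the reference table of symbols and locus tags, so genes are given by their identifiers, which the files do not pair with names. For this reason the gene lists planned before the data were examined (core clock, pathways, markers of other cell types) could not be resolved, and the tests of those lists were not run. At most 2 identifiers that rose and 2 that fell are printed for each comparison.

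The summed FPKM ran from 651475 to 749531 per library, which is not a sequencing depth. Absolute depth is unknown. Low values lay on steps of a whole read for 82.3% of 6052 low genes (tolerance 0.06 of a step), and these steps gave a relative depth between 0.794 and 1.144 times the median library. A read was worth 0.0244 FPKM in the median of those low genes, with a 5th to 95th percentile range of 0.0071 to 0.0721, so values far below 1 FPKM rest on few reads. Because gene lengths were not used, no counting interval is given for any value. Pearson's r between log2 values of replicates, across genes, ran from 0.947 to 0.9943 and was 0.98 or more in 30 of 36 pairs. The pairs of ZT40 and those of ZT44 with replicate 1 were all below 0.98. No pair of replicates within a time point shared more than 2 identical nonzero values.

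Tests used log2(FPKM + 1) for the 27449 genes with a mean of at least 1 FPKM over the 36 libraries. Fold changes are on this scale, which understates the change of low genes. All gene-wise tests were moderated tests of limma 3.58.1 (R 4.3.3) with a trend in the prior variance and Benjamini-Hochberg adjustment at 0.05, fitted over the 36 libraries. Change over the 12 time points was an F-test with time as a factor. The 24-h rhythm was an F-test of a cosine and a sine with a period of 24 h, with a term for the day. Amplitude is the distance from the middle to the peak of the fitted curve, its error is the mean standard error of the cosine and sine terms, and counts are also given for a peak-to-trough fold of at least 2. The first 24 h (ZT0 to ZT20) and the second 24 h (ZT24 to ZT44) were compared in level, with time of day as a factor, and in rhythm, by the interaction of day with cosine and sine. The amplitude ratio and the phase difference between the days are medians over the genes with a rhythm of at least 2-fold. The period per gene was the best of a grid from 18 to 32 h in steps of 0.1 h. For these medians the spread is the SD over the 3 replicate numbers fitted as separate courses, and no p-value is given. The courses share their sampling times and genes, so this SD is not the whole uncertainty.

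Named identifiers followed a rule fixed before the data were examined, with a mean of at least 10 FPKM. For the rhythm these were the 4 largest amplitudes in each of 6 peak-time bins of 4 h, with a peak within 4 h of the overall peak in each of the 3 courses. For the day level they were the 10 largest rises and 10 largest falls of the same sign at all 6 times of day, with 10 FPKM required in the higher day. For the difference in rhythm they were the 10 smallest p-values. From these, a smaller set was printed, split by direction after the data were seen. For the rhythm it was the 2 largest amplitudes among the bins around ZT0, ZT4 and ZT8 and the 2 largest among those around ZT12, ZT16 and ZT20, for the day level the 2 largest rises and the 2 largest falls, and for the difference in rhythm the 2 smallest p-values with a smaller and the 2 with a larger amplitude in the second 24 h.

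Values are given as deposited and after median-ratio rescaling, which divides each library by the median ratio of its genes to their geometric mean, because the median gene moved with time. Alternatives were other pseudocounts (0.1), filters (none, or a mean of 5 FPKM), quantile normalization, a robust prior, a replicate block, rank tests, other periods and baselines, fold minimums, and leaving out replicates, libraries or times. Leaving out 3 libraries that stood apart from the others, a covariate for them, and all alternatives for the 2-fold count, the phase difference and the share of peaks from ZT10 to ZT18 were chosen after the data were seen. Rank tests took their null from 200000 permutations of untied ranks in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

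The tests were tried on simulated data with the means and spreads of the 27449 genes and 50 changed genes per size. Noise was drawn independently for each gene and library, and all but 200 genes were flat. Deviations that many genes of a library share were thus absent, and the false calls below do not cover them. For the 24-h rhythm, 86% of genes with an amplitude of 0.25 (log2) and 100% with 0.5 were recovered, with 12 false calls. For the 12 time points, 46% and 100% of genes with those amplitudes were recovered, with 13 false calls. For the level between days, 68% of changes of 0.25 and 100% of changes of 0.5 were recovered, with 8 false calls. For a rhythm present in the second 24 h only, 36% of amplitudes of 0.25 and 90% of 0.5 were recovered, with 7 false calls. For 200 simulated genes with a period of 25 h and an amplitude of 1 (log2), 99.5% of the fitted periods were within 1 h. This limit also admits 24 h, so the share does not show that 25 h was told from 24 h. The median error was 0.2 h. Other amplitudes and a period of 24 h were not tried for the period fit.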

Results

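Transcript levels were measured in soybean unifoliolate leaves at 12 time points, every 4 h from ZT0 to ZT44, in plants that had been moved from light-dark cycles to constant conditions. There were 3 libraries per time point and 36 in all. The series asks which transcripts keep cycling when the daily change of light is gone. Of 47011 gene identifiers, 27449 had a mean of at least 1 FPKM and were tested. Relative depth ranged from 0.794 to 1.144 times the median library and absolute depth was unknown.

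Most of the leaf transcriptome changed with time. Of the 27449 genes, 26103 (95.1%) differed between the 12 time points. The first 3 principal components held 42.2%, 27.9% and 10.6% of the variance. The time point means were compared relative to each gene's own mean over time, not as levels. Those 24 h apart resembled each other, with a mean correlation across genes of 0.63 over 6 pairs (range 0.513 to 0.711). Those 12 h apart deviated in opposite directions, with a mean of -0.69 over 9 pairs (range -0.841 to -0.545). Taking out the mean of each gene itself lowers such correlations. These correlations are across genes, which are not independent replicates. The test was limma's moderated F-test with a Benjamini-Hochberg adjusted p under 0.05, and 24129 genes passed it after median-ratio rescaling. The libraries ZT40 replicate 2, ZT44 replicate 2 and ZT44 replicate 3 stood apart on the fourth component, which held 3.3% of the variance, and without them 26503 genes passed.

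**Figure D1:**
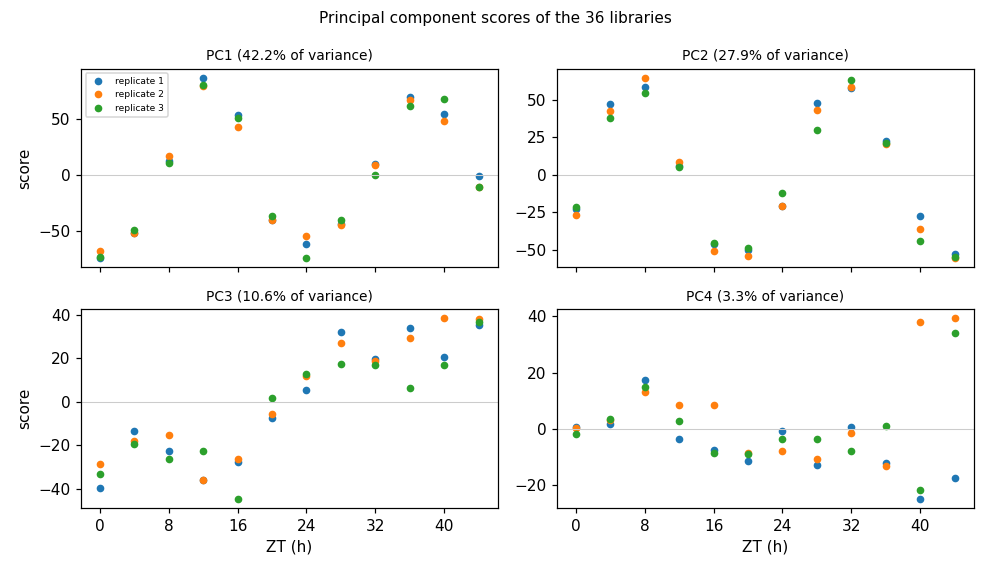
Scores of the 36 libraries on the first 4 principal components of log2(FPKM + 1) against sampling time in h (ZT), 1 point per library, coloured by replicate. On PC4 the libraries ZT40 replicate 2 (38.1), ZT44 replicate 2 (39.3) and ZT44 replicate 3 (34.0) lie above the other 33, which reach 17.6.

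The composition of the libraries itself followed the time of day. The 20 genes with the highest mean over the 36 libraries held 19.9% ± 0.57 (SD, n = 3) of the summed FPKM at ZT0, 12.3% ± 1.31 at ZT12, 18.7% ± 1.37 at ZT24 and 12.2% ± 1.39 at ZT36. The share was lowest at ZT44 (11.1% ± 2.54), where 2 abundant identifiers were listed at 0 in replicates 2 and 3. The median tested gene moved the other way, from 2.55 ± 0.03 on the log2 scale at ZT0 to 3.00 ± 0.04 at ZT16, 2.57 ± 0.10 at ZT24 and 3.02 ± 0.12 at ZT40 (SD, n = 3 each). The highest and lowest time point means differed by 0.47. The main counts that follow are therefore given both as deposited and relative to the median gene.

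**Figure D2:**
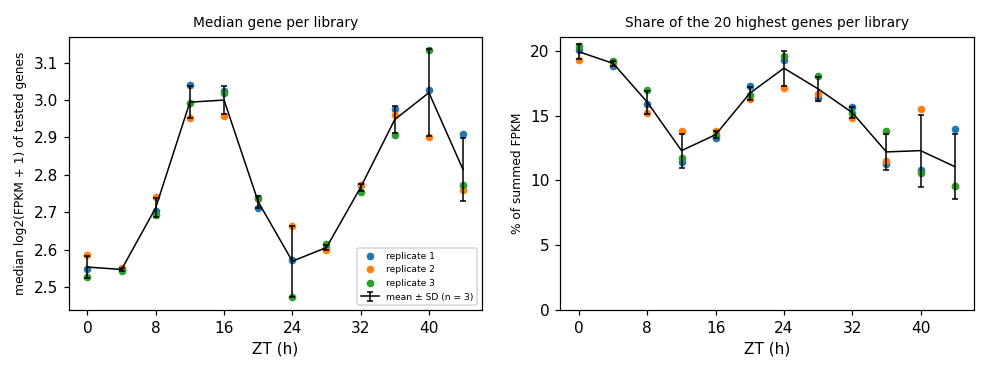
Left, median log2(FPKM + 1) of the tested genes, and right, the percentage of each library's summed FPKM held by the 20 genes with the highest mean, against sampling time in h (ZT); points are libraries coloured by replicate, and lines show the mean ± SD of 3. The median was lowest near ZT0 to ZT4 (2.55) and highest at ZT40 (3.02), while the share of the 20 highest genes was largest at ZT0 (19.9%).

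A 24-h rhythm was called for 25921 genes (94.4%), and for 23679 (86.3%) relative to the median gene. Most of these rhythms were shallow. A peak-to-trough change of at least 2-fold was found for 8142 genes (29.7%), of at least 4-fold for 1700 and of at least 8-fold for 503. The same limits gave 6137, 1655 and 537 genes relative to the median gene, and 5263 genes passed the 2-fold limit on both scales. Of these, 5239 had peaks within 2 h of each other on the 2 scales. The number of genes passing the 2-fold limit without the 3 libraries that stood apart was 8245, of which 7874 were also called with all 36.

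The distribution of peak times depended on the scale. As deposited, 60.6% of the genes with a rhythm of at least 2-fold peaked from ZT10 to ZT18, against 26.1% relative to the median gene, and the SD over the 3 replicate courses was 1.46 and 0.31 percentage points. In bins of 4 h, 2725 genes peaked around ZT16, 2205 around ZT12, 1126 around ZT20, 880 around ZT0, 793 around ZT8 and 413 around ZT4 as deposited. The largest group relative to the median gene was instead the 1609 genes that peaked around ZT0, followed by 1019 around ZT8, 996 around ZT20, 914 around ZT4, 875 around ZT12 and 724 around ZT16.

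**Figure D3:**
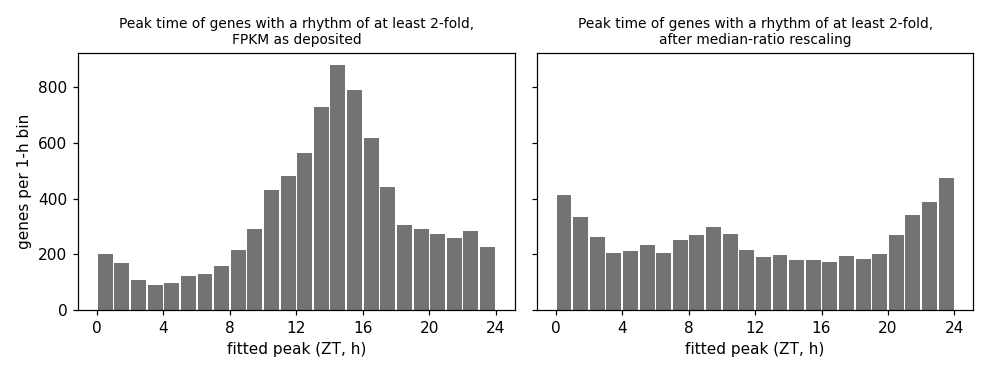
Number of genes with a 24-h rhythm of at least 2-fold per 1-h bin of the fitted peak time (ZT, h), as deposited (left, 8142 genes) and after median-ratio rescaling (right, 6137 genes). The fullest bin starts at ZT14 as deposited (878 genes) and at ZT23 after rescaling (475 genes).

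The ZT0 group had a median peak-to-trough fold of 3.4 (quartiles 2.52 and 5.49) and 129 of its 880 genes passed 8-fold. The ZT4 group had a median fold of 3.17 and 60 of its 413 genes passed 8-fold. The ZT12 group had a median fold of 2.59 with 153 of 2205 genes above 8-fold, and the ZT16 group had the lowest median, 2.4 (quartiles 2.16 and 2.96), with 44 of 2725 above 8-fold. Relative to the median gene the ZT0 group kept the largest median fold (3.14) and the ZT16 group the smallest (2.51). On that scale the genes above 8-fold were 191 of 1609 in the ZT0 group, 105 of 914 in the ZT4 group, 97 of 875 in the ZT12 group and 17 of 724 in the ZT16 group. Genes with a mean of at least 100 FPKM made up 112 of the ZT0 group and 65 of the ZT16 group as deposited, and 169 and 17 after rescaling. The group medians describe the sets, and the differences between groups were not tested.

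Among the 24 identifiers that met the naming rule for the rhythm, amplitudes ran from 2.42 to 3.67 on the log2 scale, or 28.8-fold to 163-fold from trough to peak, and all had adjusted p-values of 7.98e-10 or less (limma). GLYMA06G38160 peaked at ZT7.9 with an amplitude of 3.59 ± 0.10 (SE, adjusted p = 6.87e-26). Its level rose from 43.9 ± 5.37 FPKM at ZT0 to 1730 ± 48.2 at ZT8 and fell to 7.54 ± 0.677 at ZT20 (SD, n = 3), and on the next day it reached 1060 ± 230.0 at ZT32. GLYMA16G27995 peaked at ZT6.2 with an amplitude of 3.08 ± 0.16 (SE, adjusted p = 2.58e-18), between 2350 ± 409 FPKM at ZT8 and 28.2 ± 9.83 at ZT16. GLYMA19G27530 peaked at ZT12.0 with an amplitude of 3.67 ± 0.17 (SE, adjusted p = 9.51e-20), from 5.76 ± 1.14 FPKM at ZT0 to 2650 ± 335 at ZT12 and 2830 ± 338 at ZT36. GLYMA06G35550 peaked at ZT11.8 with an amplitude of 3.67 ± 0.11 (SE, adjusted p = 6.07e-25), from 0.581 ± 0.0313 FPKM at ZT0 to 352 ± 22.5 at ZT12 and 360 ± 46.1 at ZT36. Relative to the median gene these 4 amplitudes were 3.63, 3.24, 3.45 and 3.49.

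**Figure D4:**
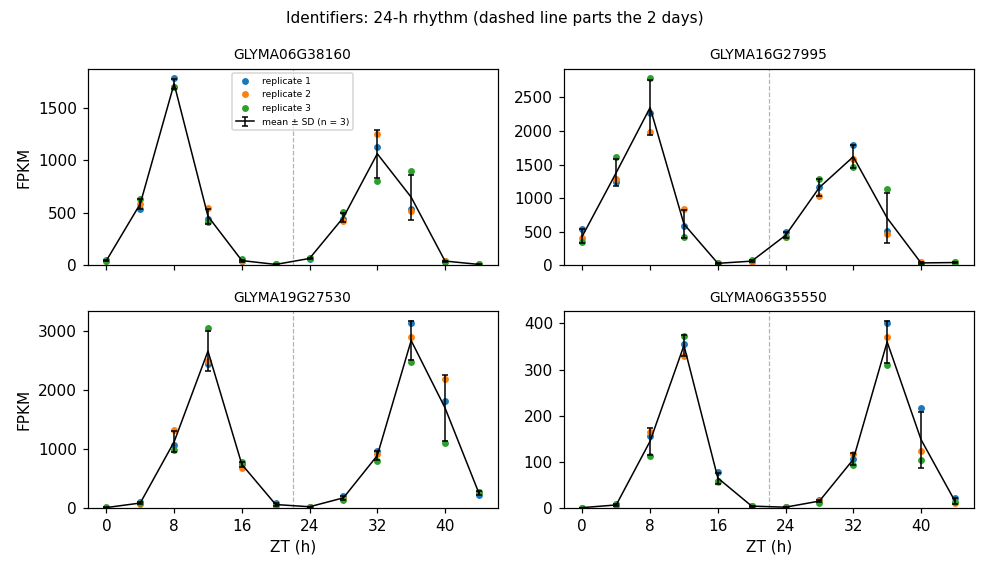
FPKM of 4 identifiers with a large 24-h rhythm against sampling time in h (ZT); points are libraries coloured by replicate, lines show the mean ± SD of 3, and the dashed line parts the 2 days. The upper pair peaks at ZT8 on the first day, GLYMA06G38160 at 1730 FPKM, and the lower pair at ZT12, GLYMA19G27530 at 2650 FPKM.

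Levels at matched times of day also differed between the 2 days. In the second 24 h 8189 genes were higher and 5164 were lower, so that 61.3% of the calls were rises. Relative to the median gene 6582 were higher and 6703 were lower, with 49.5% rises, and 11746 genes were called with the same sign on both scales. The changes were small for most genes: 798 rose and 664 fell by at least 1.5-fold, and 116 rose and 156 fell by at least 2-fold. Relative to the median gene the balance at 1.5-fold turned, with 662 rises and 749 falls, and at 2-fold there were 99 rises and 168 falls. The test was limma's moderated test of the day term with time of day as a factor. The 3 libraries that stood apart all belong to the second 24 h, and without them 8904 genes were higher and 5187 lower. Plant age and time in constant conditions increased together, and the design does not separate them.

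Among the 20 identifiers named for the day level, differences ran from 2.02 to 3.14 on the log2 scale for rises and from -3.23 to -1.84 for falls. GLYMA02G37990 was higher by 3.14 ± 0.21 (SE, adjusted p = 4.9e-13). Its mean stayed between 3.11 and 6.59 FPKM from ZT0 to ZT16, was 68.8 ± 45.1 at ZT20 and reached 178 ± 15.3 at ZT44 (SD, n = 3). GLYMA06G11790 was higher by 2.63 ± 0.18 (SE, adjusted p = 5.44e-13), from 1.44 ± 0.109 FPKM at ZT0 to 25.7 ± 3.0 at ZT24. GLYMA19G43940 fell by 3.23 ± 0.30 (SE, adjusted p = 1.46e-10), with 84.8 ± 56.4 FPKM at ZT16 and 3.47 ± 4.79 at ZT40. GLYMA03G41330 fell by 2.55 ± 0.34 (SE, adjusted p = 2.18e-07), with 60.4 ± 30.8 FPKM at ZT16 and 5.02 ± 7.78 at ZT40. For both falling identifiers the mean at ZT40 rested on replicate 3: GLYMA19G43940 was at 9.00 FPKM there against 0.818 and 0.596 in replicates 1 and 2, and GLYMA03G41330 was at 14.0 against 0.535 and 0.523.

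**Figure D5:**
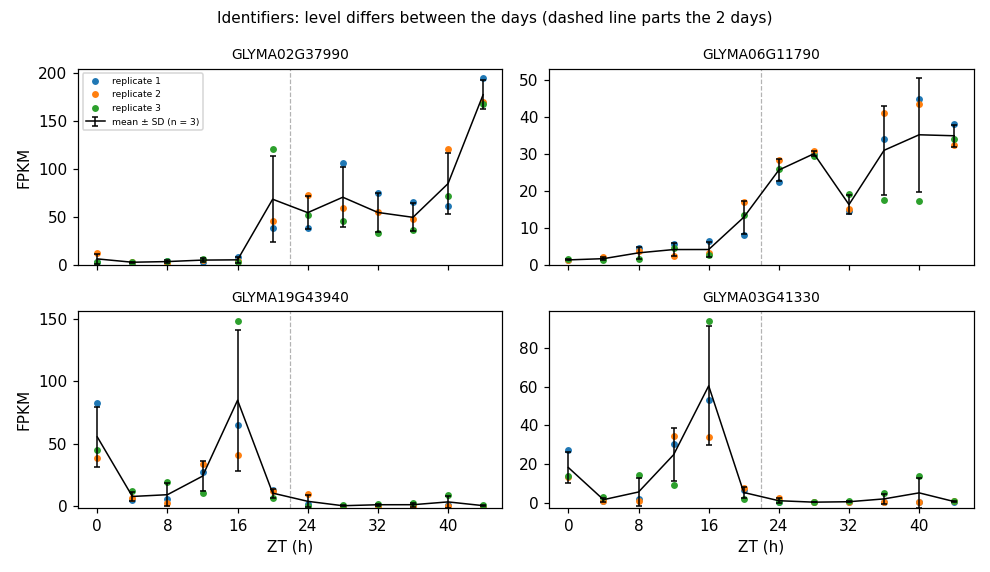
FPKM of 4 identifiers whose level differed between the days against sampling time in h (ZT); points are libraries coloured by replicate, lines show the mean ± SD of 3, and the dashed line parts the 2 days. The upper pair was higher in the second 24 h, with GLYMA02G37990 at 178 FPKM at ZT44, and the lower pair was lower, with GLYMA19G43940 at 84.8 FPKM at ZT16 and 3.47 at ZT40.

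The rhythm itself differed between the days for 4214 genes (15.4%), and for 4077 relative to the median gene. The amplitude was smaller in the second 24 h for 3142 of the 4214 genes and larger for 1072, and for 2925 and 1152 of the 4077 genes after rescaling. Over all genes with a rhythm of at least 2-fold, the median amplitude ratio of the second to the first 24 h was 0.893, with an SD of 0.038 over the 3 replicate courses (0.876, 0.882 and 0.944), and 71.0% of the genes (68.6% after rescaling) had the smaller amplitude in the second 24 h. As deposited the ZT0 group had the lowest median ratio, 0.846, and the ZT4 group the highest, 0.951. After rescaling these groups had 0.865 and 0.938, and the extremes were the ZT12 group (0.852) and the ZT16 group (0.955). The test of single genes was limma's F-test of the interaction of day and rhythm. Its count changed with the libraries used: it was 752, 515 and 1456 without replicates 1, 2 and 3, and 2625 without ZT44. With 1 library left out it ran from 3381 (ZT44 replicate 3) to 4992 (ZT24 replicate 3). The count differed between fits with equal numbers of libraries, so their number alone does not set it. Without the 3 libraries that stood apart it was 3163, of which 2663 were also called with all 36.

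The genes with a rhythm of at least 2-fold peaked later on the second day, by a median of 0.79 h with an SD of 0.055 h over the 3 courses (0.833, 0.722 and 0.774 h). This SD leaves out error shared by the libraries of a time point. Leaving out single time points moved the delay further, from 0.545 h without ZT20 to 1.009 h without ZT8. The peak was later for 79.7% of the genes (77.1% after rescaling). The median delay was 1.08 h in the ZT16 group, 0.92 h in the ZT0 group, 0.88 h in the ZT4 group, 0.73 h in the ZT12 group, 0.39 h in the ZT8 group and 0.38 h in the ZT20 group. The best-fitting period had a median of 24.5 h, with an SD of 0.115 h over the 3 courses and quartiles over genes of 23.9 and 25.1 h. Relative to the median gene the median delay was 0.703 h and the median period 24.5 h. A sampling step of 4 h over 2 cycles resolves these values only as medians over many genes.

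Of the 10 identifiers named for a difference in rhythm, 8 had the smaller and 2 the larger amplitude in the second 24 h. GLYMA03G27970 had an amplitude of 0.82 (log2) in the first and 0.47 in the second 24 h with a peak 2.28 h later (adjusted p = 2.12e-07, limma interaction). Its mean was 138 ± 5.41 FPKM at ZT12 and 99.4 ± 2.46 at ZT36 (SD, n = 3). GLYMA06G42080 had amplitudes of 1.69 and 1.39 with a peak 2.3 h later (adjusted p = 4.97e-07), and its level at ZT44 was 25.5 ± 2.44 FPKM against 22.1 ± 4.69 at ZT20. GLYMA16G01220 had amplitudes of 0.34 and 0.49 with a peak shift of -11.13 h (adjusted p = 9.22e-06). Its curves on the 2 days were thus nearly opposed as deposited, with 7.28 ± 0.869 FPKM at ZT4 and 16.5 ± 4.5 at ZT28. The peak shift relative to the median gene is not given here. Over both days no 24-h rhythm was called for it as deposited (adjusted p = 0.593, limma F-test). Relative to the median gene 1 was called (adjusted p = 0.00467). The amplitude difference of GLYMA16G01220 between the days, 0.147 as deposited, depended on the setting. It was 0.547 relative to the median gene, 0.523 with quantile normalization, 0.093 without replicate 2 and 0.227 without replicate 3. With a covariate for the 3 libraries that stood apart it was 0.095. GLYMA10G03840 had amplitudes of 0.39 and 0.67 with peaks 8.68 h apart (adjusted p = 9.68e-06), with 31.7 ± 7.66 FPKM at ZT0 and 12.4 ± 0.848 at ZT24. Its amplitude difference of 0.28 between the second and the first day became -0.214 relative to the median gene and -0.121 with quantile normalization.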

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

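The range tests of depth, the matching of the 3 libraries to time points, the amplitudes without the 20 and the 100 highest genes and with depth as a covariate, the tests without the 3 libraries and without single time points, and the counts over random splits were chosen after the results were seen. The difference in rhythm between the days was tested by an interaction and is listed here because the days differed: 4214 genes passed, among them GLYMA03G27970 (adjusted p = 2.12e-07), GLYMA06G42080 (4.97e-07), GLYMA16G01220 (9.22e-06) and GLYMA10G03840 (9.68e-06).

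Libraries were randomly reassigned to time points for the time point and rhythm tests, and day was swapped within time of day for the others. For each of the 4 tests 1 of 100 splits, the real one, gave as many genes, which is the smallest share possible. Random assignment of single libraries is thus an unlikely source of these counts. Variation shared by all libraries of a time point or of a day is not covered by these splits. The highest other split gave 18 genes against 26103 for the 12 time points, 3338 against 25921 for the rhythm, 0 against 13353 for the level between the days and 52 against 4214 for the rhythm between the days.

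The level of the median gene followed a 24-h course with an amplitude of 0.244 (log2). The 20 highest genes alone do not account for it, since the amplitude was 0.206 per FPKM outside them, nor do the 3 libraries that stood apart (0.251 without them) or depth (0.24 with relative depth as a covariate). The correlation of depth with the library median over 36 libraries lay on the limit set beforehand and decides nothing alone (r = -0.3, permutation p = 0.076, Spearman's rho = -0.226, p = 0.184, and r = -0.133 without the 2 libraries farthest from the median depth). Outside the 100 highest genes the amplitude was 0.13, and outside the 1000 highest, which held 65.9% of the FPKM at the time point where they held most and 50.5% where they held least, it was 0.053. These tests divide by the total of the other genes, and with more genes removed they increasingly centre on the median gene itself, so whether abundant transcripts fell or the others rose per cell cannot be told apart from relative values.

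The libraries ZT40 replicate 2, ZT44 replicate 2 and ZT44 replicate 3 stood apart on the fourth principal component, with scores of 38.1, 39.3 and 34.0 against -24.8 to 17.6 in the other 33. At ZT44, replicates 2 and 3 had the highest r of all replicate pairs (0.9943). Replicate 1 had 0.9686 and 0.9721 with them, so within ZT44 it can equally be called the one apart. At ZT40 the pairs without and with replicate 2 were all low (0.969, 0.9624 and 0.947). Depth outside the range of the others was found in 0 of the 3, with relative depths of 0.97 to 1.096. The step size of short genes, meant to show fragment length, lay outside that range in 0 of the 3. It would move with fragment length only if the FPKM corrected gene length for fragment size, which is not known. Fragment length therefore stays open. A mislabelled time point was tested by matching each to the mean profiles of the other 33. The best match lay over 4 h from the label for 0 of the 3, and each matched its own time point best. The r across genes of these matches was 0.564 to 0.653, and for ZT44 the mean is replicate 1 alone. The same ZT44 libraries had an r of 0.9686 and 0.9721 with replicate 1 above, so the match r is not one of levels. The 2 kinds of r cannot be compared. The labels give no batch or date, so a shared preparation or a difference between the pooled plants stays open, and no biological explanation was tested.

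The later peak on the second day (median 0.79 h) was not due to the 3 libraries, without which it was 0.852 h, nor to the scaling, since it was 0.703 h relative to the median gene. Mistimed sampling at a single time point stays open: without ZT20 the delay was 0.545 h, the lowest of the 12, and without ZT8 it was 1.009 h. A free-running period longer than 24 h in constant conditions is a hypothesis that may account for a delay of this sign in all 6 peak-time groups. A period common to all genes would give every group the same delay. The group medians ran from 0.38 h (ZT20 group) to 1.08 h (ZT16 group), and their differences were not tested. The hypothesis was not tested apart from plant age, which rose with time.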

How the results depend on the processing

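Alternatives for the 2-fold count, the phase difference and the share of peaks from ZT10 to ZT18, and those concerning the 3 libraries, were chosen after the data were seen. Of 550 summary values under alternatives, 519 stayed within 1.5 times the count or within 1 SD over the replicate courses. Most of the 550 only left out a replicate or a library. Under the other alternatives 9 of 20 values stayed for the phase difference and 3 of 6 for the share of peaks, against 15 of 15 for the 2-fold count. The limit of 1.5 times also passed the rescaled day counts, 6582 higher and 6703 lower against 8189 and 5164, where the balance was lost. Of 108 values for the 12 named identifiers, 106 kept their sign and call; the amplitude difference of GLYMA10G03840 changed sign to -0.214 with median-ratio rescaling and to -0.121 with quantile normalization, and the cause was not tested. With a mean of at least 5 FPKM fewer genes were tested, and counts were 15152 (time points), 15015 (rhythm), 8131 (day level), 5301 higher and 2830 lower. With a fold of at least 1.5 the day level gave 1462 genes, 798 higher and 664 lower, and a fold of at least 2 gave 8142 rhythms. Quantile normalization gave 6900 higher and 6619 lower.

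The share of peaks from ZT10 to ZT18 (60.6%) was 64.2% with a pseudocount of 0.1, 26.1% with median-ratio rescaling and 29.8% with quantile normalization, and 58.0 to 63.7% with a replicate or library left out. The count of differing rhythms was 2625 without ZT44, a setting with fewer samples, and reached 6249 among the other alternatives. It was 515 to 4992 with a replicate or library left out, the lowest being without replicate 2. The delay of 0.79 h was 0.734 h with a pseudocount of 0.1, 0.703 h rescaled, 0.707 h at a fold of at least 1.5, 0.852 h without the 3 libraries, 0.849 h with a covariate for them, and 0.725 to 0.845 h with a replicate or library left out. Without ZT0, ZT8, ZT12, ZT20, ZT28 and ZT32 it was 0.942, 1.009, 0.68, 0.545, 0.899 and 0.637 h. The period implied by the delay was 24.79 h against 24.5 h fitted. Some of these settings used fewer samples or genes, and the causes were not tested.

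Rank tests gave 26116 genes for the time points and 25196 for the rhythm. They used the FPKM as deposited with no term for the day, so the course of the median gene stayed in these counts. With the replicate block, counts were 26137, 25909, 13299 and 4049 for the 4 tests. The numbers were not taken as pairs, since 42 of 198 same-numbered pairs of libraries, not all, had a correlation of deviations above 0.1 (median 0.006, range -0.32 to 0.603). A library of the same number was the closest match of 20 of 36 libraries, against 12 expected by chance, so some sharing by number is not excluded. Tests of gene lists were not run because no identifier matched a name. Relative depth was known only from low values, so no limit from counting can be set for low genes.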

Other observations

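The neighbour and chromosome tests below were written down before their results were seen, except for the rotation of the gene order, the larger distances and the rescaled values. Rhythm was also counted by level. Of 89 genes with a mean above 1000 FPKM, 56 (62.9%) had a rhythm of at least 2-fold as deposited and 75 (84.3%) relative to the median gene, against 2516 (21.3%) and 1798 (15.2%) of the 11822 genes between 1 and 5 FPKM. Few of the rhythmic genes above 1000 FPKM peaked from ZT10 to ZT18, 5.4% as deposited and 2.7% rescaled, against 64.4% and 28.4% of those between 1 and 5 FPKM. The difference between these classes was not tested, and it was measured on the log2(FPKM + 1) scale, which compresses folds of genes near 1 FPKM: with a pseudocount of 0.1 the 2-fold count over all classes was 11264 in place of 8142.

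GLYMA19G06370 and GLYMA19G06340, the identifiers with the highest mean in the table and chosen here after their values were seen, were listed at 0 in ZT44 replicates 2 and 3. In ZT44 replicate 1 they were at 24210.5 and 20117.6 FPKM, and in ZT40 replicates 1, 2 and 3 GLYMA19G06370 was at 18177.9, 35467.1 and 20164.9 FPKM. A value of 0 in a table without counts can be a failed estimate, and these libraries belong to the 3 that stood apart.

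Genes whose identifiers lie next to each other peaked at more similar times than random pairs. Over 1635 adjacent pairs in which both genes had a rhythm of at least 2-fold, the mean distance between peaks was 3.848 h, against 4.90 to 5.38 h in 1000 random orders, and 39.9% of pairs peaked within 2 h of each other. The distance was 4.545 h for identifiers 2 apart, below the lowest random value of 4.84 h, and 4.694 h for identifiers 3 apart, below the lowest of 4.882 h. At 5 apart it was 4.921 h, with 6 of 1000 random orders as low, and at 10 apart it was 5.065 h, with 187 of 1000 as low. After rescaling, adjacent pairs were 4.15 h apart against 5.58 to 6.23 h in random orders. Copies or reads shared by adjacent gene models may give this similarity, and an array of copies can run over more than 2 identifiers, so the values at distances of 2 and 3 do not exclude them; sequences were not used here.

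The share of genes with a rhythm of at least 2-fold ran from 27.4% on chromosome 16 to 31.8% on chromosome 11, with the chromosome read from the identifier. The chi-square of the 20 shares was 21.67, below the 95th percentile of 10000 permutations of the genes (30.26; permutation p = 0.304), so no difference between chromosomes was found as deposited. After rescaling the chi-square was 44.12 with a permutation p of 0.0012, but p was 0.184 when the order of genes was kept and only rotated, which keeps neighbours together.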
